A study of Mus musculus with 4 samples.

How the data were processed

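Total RNA of mouse neural stem cells was made into libraries with QuantSeq, a kit that reads messenger RNA from the 3′ end, per the labels' protocols. The 4 libraries were grouped by the guide in their labels, 2 with sgCtrl and 2 with sgFosl1. Per the submitters' processing notes, STAR 2.5 and HTSeq were used with the mouse genome GRCm38 (mm10). The annotation version, the strand setting of the counting and the scaling method were not given in the sources used here. Without the strand setting, values of overlapping and antisense genes are uncertain.

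The deposited signal is a table of read counts per gene divided by 1 factor per library, as normalised by the authors. In each library the values were whole multiples of what 1 read was worth, and 100% of values came out whole at a tolerance below 0.001. The recovered factors were 1.00357 and 0.961355 for sgCtrl and 1.03395 and 1.03143 for sgFosl1, and median-of-ratios factors computed from the recovered reads were equal to these at the digits given. For sgCtrl replicate 1, whose step lies close to 1, an automated test of the recovery could not decide, and its reads were recovered in the same way. The table listed 47643 gene identifiers, of which 47224 matched a symbol in the reference name table, 19198 had a read in at least 1 library, and 16219, 15693, 15785 and 15686 had a read in sgCtrl replicates 1 and 2 and sgFosl1 replicates 1 and 2. The 25 genes with most reads took 12%, 12.8%, 10.4% and 11.9% of them. Gene coordinates are those of the GENCODE M21 annotation of GRCm38. The transgenes Cas9, Cre and Tva were not analysed here.

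Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend and the group as the only term, on the 11701 genes with a value of at least 10 in at least 2 libraries. Of these, 17 had no symbol. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05. The residual degrees of freedom were 2 and the prior ones 4.16. Fold changes on this scale understate the change of low genes. The log2 change is sgFosl1 minus sgCtrl. Where a group held 1 to 3 reads, the ratio is given with an exact 95% counting interval, and where it held none, as a bound against 3 reads per library, worth a value of 2.99, 3.12, 2.9 and 2.91 in sgCtrl replicates 1 and 2 and sgFosl1 replicates 1 and 2. The kit's reads were not counted by molecular identifiers as far as the sources state, so intervals and floors cover counting error only. The replicates of each group differed by more than sampling noise (chi-square per degree of freedom 21.1 in sgCtrl and 5.11 in sgFosl1) and were counted as separate libraries.

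Before the data were examined, 34 gene lists and the rule for named genes were fixed. The lists were compiled from general knowledge of the field, share some members, and were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance 1 way and compares no other genes, were run beside it. No list call held with the estimated correlation. Counts given per list cover its tested members only, and listed members below the filter are left out. Named genes were Fosl1, Kras and Trp53, the 10 genes with the largest change in each direction among those past the threshold with a mean of at least 50 in the higher group and no overlap of the groups, and up to 4 members per list with the smallest adjusted p. Members given only by name as the ones that rose, fell or went against their list were chosen after their values were seen. Predicted genes and pseudogenes were not named in the second group.

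The steps were tested on simulated counts for sgFosl1 against sgCtrl (11592 genes, dispersion 0.0564, 50 genes per fold size). Changes were placed only in genes with a mean of at least 50. Limma recovered 22% of 2-fold changes and 100% of 4-, 8- and 16-fold changes, with 2 false calls. Of 200 unchanged lists, 1 was called by camera at an unadjusted p below 0.05. Genes were drawn independently with 1 dispersion for all, so this does not check list calls where members move together. In the real lists the estimated correlation was as high as 0.737 (astrocyte). The alternatives were other pseudocounts, filters, scalings and limma settings, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, a minimum log2 change, each library left out, and the replicate number as a block. When a library was left out as planned, the filter was reapplied to the libraries left, which removed genes seen mainly in the reduced group. Leaving out each library with the same 11701 genes tested was therefore added after the planned values had been seen, as were list member counts without each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.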

Results

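The transcriptomes of mouse neural stem cells were compared after Cas9 was directed to Fosl1 or given a control guide. Neural stem cells are self-renewing brain cells that can form neurons, astrocytes and oligodendrocytes. Per the labels, these cells carried Cas9 and floxed Trp53 alleles and had received a mutant Kras before the guides. The guide is the short RNA that sets where Cas9 cuts. Messenger RNA was measured by sequencing from transcript 3′ ends in 2 libraries with the control guide (sgCtrl) and 2 with the Fosl1 guide (sgFosl1). The recovered depth was 3248556 and 3375266 reads in sgCtrl replicates 1 and 2, and 3220918 and 3265905 reads in sgFosl1 replicates 1 and 2. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

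The series title places Fosl1, which encodes the AP-1 transcription factor subunit FRA-1, in the plasticity of mesenchymal glioblastoma, and the comparison asks how expression differs when Fosl1 is targeted. Fosl1 (ENSMUSG00000024912; GRCm38 chromosome 19, 5447547 to 5455946, plus strand, protein coding) fell from a normalised read count of 204 ± 66.6 (SD, n = 2) in sgCtrl to 0.968 ± 0.0017 (SD, n = 2) in sgFosl1. The 4 libraries held 157, 241, 1 and 1 Fosl1 reads, in the order given for the depths. The ratio was 209, with a 95% counting interval from 57.5 to 1733, and the log2 change was −6.66 ± 0.44 (SE; limma, adjusted p = 0.000757). The guide's cut site was not given in the sources used here, and a small deletion outside the transcript end need not remove 3′ reads. Kras (ENSMUSG00000030265; chromosome 6, 145216699 to 145250239, minus strand), the gene of a small GTPase upstream of the MAPK cascade, fell from 3149 ± 2094 to 459 ± 15 (SD, n = 2 each). Its log2 change was −2.60 ± 0.45 (SE; limma, adjusted p = 0.00836), and reads of the introduced and the native gene were not separated. The Kras call was lost when either sgFosl1 library was left out, both with the filter reapplied and with the same genes tested. Its log2 change was then −2.63 without replicate 1 and −2.56 without replicate 2. The Kras call was also lost without the filter on low values (limma, adjusted p = 0.0614). Trp53 had 10.5 ± 11.9 in sgCtrl and 38.7 ± 6.91 in sgFosl1 (SD, n = 2 each) and did not pass (limma, adjusted p = 0.0811). It passed with a pseudocount of 10 (adjusted p = 0.04), with quantile normalization (0.0496) and without sgCtrl replicate 1 (0.0117 with the same genes tested). Its 3′ reads check nothing about a deletion elsewhere in the gene.

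Expression differed widely between the groups. Of 11701 genes tested, 4352 changed (limma, adjusted p below 0.05), 2074 of them higher and 2278 lower in sgFosl1. The change was at least 8-fold on the log2 scale for 503 higher and 619 lower genes. Both libraries of one group lay above both of the other for 8699 genes, or 74.3%, where chance gives each gene 33.3%. Genes are not independent, so the share over genes is no test against chance. Across genes, which are not independent replicates, Pearson's r was 0.935 within the sgCtrl pair and 0.977 within the sgFosl1 pair. Between groups, r was 0.740 and 0.729 for sgCtrl replicate 1 and 0.631 and 0.625 for sgCtrl replicate 2, so replicate 1 lay nearer to the sgFosl1 libraries. The number of changed genes depended on single libraries. With the low-value filter reapplied to the libraries left, it was 1018 (202 higher, 816 lower) without sgFosl1 replicate 1 and 840 (165 higher, 675 lower) without sgFosl1 replicate 2. With the same 11701 genes tested, it was 410 (38 higher, 372 lower) and 267 (25 higher, 242 lower). In those fits the spread came from the sgCtrl pair alone, and in fits without an sgCtrl library from the sgFosl1 pair alone. Without sgCtrl replicate 1 the count was 5816 with the filter reapplied, 3185 of them higher, and 4861 with the same genes. Without the low-value filter, 2237 of 19198 genes changed.

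The largest upward change was in Slc6a11. This gene, which encodes a GABA transporter of astrocytes, rose from 12 ± 16.9 to 2541 ± 193 (SD, n = 2 each; log2 change 8.99 ± 1.34 SE). Hes5, a Notch target of neural progenitors, rose from 258 ± 351 to 6032 ± 133, and Adcyap1r1, which encodes a receptor of the neuropeptide PACAP, from 35.5 ± 44.3 to 1561 ± 97.9. Helt, a transcription factor gene of the developing midbrain, rose from 18.5 ± 24.6 to 1116 ± 428. Nlgn3, Celf3, Prkcq and Rimklb completed the genes with more than 3 sgCtrl reads, at log2 changes of 6.64, 6.60, 6.57 and 6.25. Gjc3 had 2 sgCtrl reads and was 213 times higher in sgFosl1 (95% counting interval 58.5 to 1761), and Nebl had 1 and was 205 times higher (36.5 to 8154). Limma's adjusted p for these 10 genes ran from 0.00141 (Nebl) to 0.0253 (Hes5). The Hes5 call was lost with DESeq2 (adjusted p = 0.0532), with robust limma (0.123), with limma without trend (0.0574) and without the low-value filter (0.115). Helt, Adcyap1r1 and Rimklb were also lost with robust limma (0.0621, 0.0565 and 0.0578), and Rimklb with DESeq2 (0.0617). Without the filter, Helt (0.0668), Adcyap1r1 (0.0621), Rimklb (0.0773) and Slc6a11 (0.0537) were lost as well. With the same genes tested, 8 of the 10 lost their call without sgFosl1 replicate 1 and 9 without sgFosl1 replicate 2.

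The largest downward changes were in genes nearly without reads in sgFosl1. Spp1, which encodes the matrix protein osteopontin, fell from 856 ± 644 (SD, n = 2) to 3 reads in the sgFosl1 pair, a ratio of 583 (95% counting interval 199 to 2828). Epha2, which encodes an ephrin receptor kinase, had 222 ± 155 in sgCtrl and no read in sgFosl1, and was at least 76.5-fold lower against a floor of 3 reads per library. Dkk2, which encodes a Wnt regulator, fell from 381 ± 50.5 at a ratio of 393 (108 to 3252), and Nptx2, which encodes a neuronal pentraxin, from 479 ± 45.5 at a ratio of 329 (112 to 1598). Il34, the gene of a ligand of the CSF1 receptor, fell from 226 ± 110.5 at a ratio of 463 (82.6 to 18309). Syne3 fell at a ratio of 614 (170 to 5079), Trbc2 at 351 (119.9 to 1707), Arhgap22 at 720.0 (129 to 28480), Cdsn at 876 (157 to 34625) and Scn5a at 459 (82 to 18184). Trbc2 has a near-identical neighbouring copy, and its value is uncertain where reads could be split between them. Limma's adjusted p for these 10 genes ran from 0.000556 (Nptx2) to 0.00401 (Cdsn), and Cdsn lost its call with the same genes tested without sgFosl1 replicate 1 (0.0627) or replicate 2 (0.0775).

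**Figure D1:**
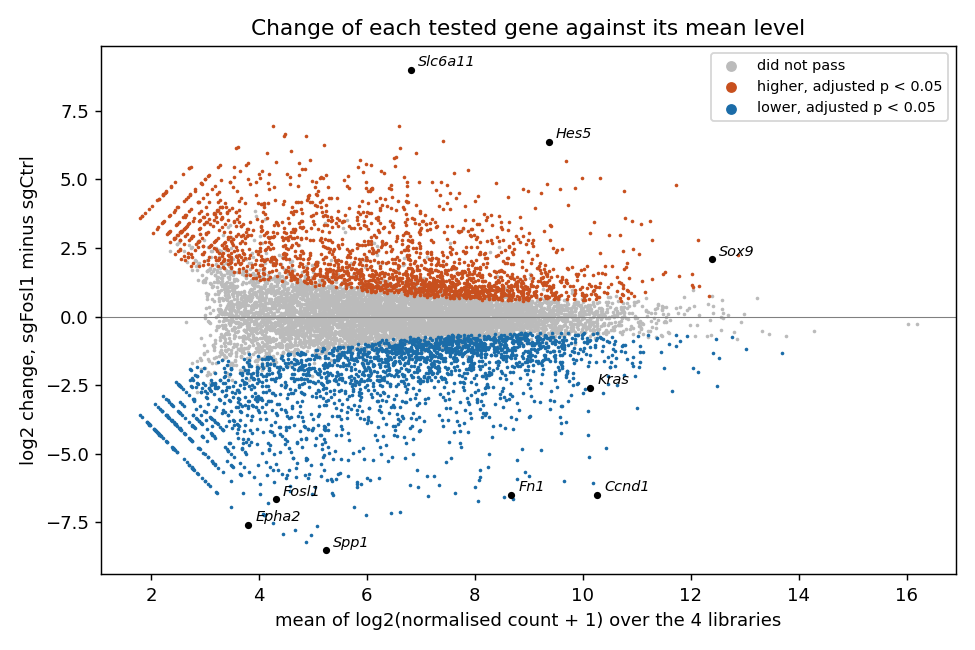
Log2 change (sgFosl1 minus sgCtrl) of each of the 11701 tested genes against its mean log2(normalised count + 1) over the 4 libraries. Orange points are the 2074 higher and blue points the 2278 lower genes at a limma adjusted p below 0.05, grey points did not pass, and 9 named genes are drawn in black.

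Genes of the AP-1 family and of the mesenchymal glioblastoma signature were mostly lower in sgFosl1. The signature is a set of genes high in the tumour subtype with mesenchymal and wound-like expression. Jun fell from 1961 ± 431 to 235 ± 20.8, Junb from 564 ± 91.5 to 46 ± 11.7, and Fosl2 from 1070.3 ± 505 to 109 ± 17.6 (SD, n = 2 each). Runx1, a transcription factor gene, fell from 381 ± 97.9 to 5.81 ± 1.38, the adhesion receptor gene Cd44 from 1527 ± 888 to 90.5 ± 27.9, and the stress-response gene Ndrg1 from 405 ± 49.6 to 19.4 ± 1.34. Of 16 AP-1 members tested, 11 fell, 2 rose and 3 did not pass, with the same counts adjusted over the list alone (median log2 change −2.26, camera adjusted p = 7.53e-04, adjusted p = 0.249 with an estimated correlation). This list holds the targeted gene. Of 65 mesenchymal members, 41 were tested. Of these 41, 32 fell, 2 rose (Stat3 and Bace2) and 7 did not pass, and 32 and 2 adjusted over the list alone. The median was −3.20 (camera adjusted p = 2.03e-10, adjusted p = 0.296 with an estimated correlation), or −2.94 with genes lacking reads in a group at their bound. Of 11 tested genes of epithelial-mesenchymal transition (EMT), 7 fell and 4 did not pass, also over the list alone, with a median of −2.48 (camera adjusted p = 5.22e-03, adjusted p = 0.283 with an estimated correlation). Among them Fn1, which encodes fibronectin, fell from 4044 ± 1624 to 44 ± 18.4, and Prrx1 from 884 ± 174 to 66.8 ± 1.25, but Cdh1, a marker of epithelia rather than mesenchyme, also fell (log2 change −2.48). With the same genes tested, 14 mesenchymal members passed as lower without sgFosl1 replicate 1 and 8 without replicate 2, and 4 and 3 AP-1 members, and 3 and 3 EMT members, while 0 members of these lists passed as higher in either case. Without sgCtrl replicate 2, 1 AP-1 and 0 mesenchymal members passed as higher. The mesenchymal list differed by a median of −0.365 between sgCtrl replicates 1 and 2. The EMT call was lost without sgCtrl replicate 1 (adjusted p = 0.0639 with the same genes, and 0.237 with the filter reapplied, where the median was 0.397) and with a filter at 50 (0.147).

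Collagen, matrix, integrin and adhesion genes were mostly lower in sgFosl1. Igfbp3, which encodes a secreted growth factor binding protein, fell from 4072 ± 1895 to 67.8 ± 12.2 and Tgfbi, a matrix protein gene, from 241 ± 107 to 2.9 ± 0.005, whereas the cartilage collagen gene Col9a3 rose from 11.6 ± 4.68 to 482 ± 8.07 (SD, n = 2 each). Actn1, which encodes an actin crosslinker at adhesions, fell from 4857 ± 273 to 245 ± 46.8. Of 46 collagen and matrix genes, 32 fell, 7 rose and 7 did not pass, and 34 and 7 adjusted over the list alone (median −2.31, camera adjusted p = 2.41e-06, adjusted p = 0.249 with an estimated correlation). Of 26 integrin and adhesion genes, 20 fell, 2 rose and 4 did not pass, and 21 and 3 adjusted over the list alone (median −1.43, camera adjusted p = 8.95e-06, adjusted p = 0.249 with an estimated correlation). Of 28 proteases and inhibitors, 13 fell, 6 rose and 9 did not pass, and 14 and 6 adjusted over the list alone, and the list did not pass (median −0.858, camera adjusted p = 0.0579; 0.337 with an estimated correlation). The protease inhibitor gene Timp2 fell from 6648 ± 1370.1 to 650.2 ± 46.1, and Plat, which encodes tissue plasminogen activator, rose from 96.8 ± 8.7 to 713 ± 195. Without sgFosl1 replicates 1 and 2, with the same genes, 12 and 7 matrix genes, 4 and 1 adhesion genes and 2 and 1 proteases or inhibitors passed as lower, and 2 and 1 matrix genes, 0 and 0 adhesion genes and 1 and 1 proteases or inhibitors as higher. The protease list passed without sgFosl1 replicate 2 (adjusted p = 0.0316), without sgCtrl replicate 2 (0.0275), with equal totals (0.0356), with quantile normalization (0.0497), without a filter (0.0242) and with fry (0.0117).

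Among genes of the proneural and classical glioblastoma signatures and of neural stem cells, more rose than fell in sgFosl1. The 2 signatures describe tumour subtypes with oligodendrocyte-progenitor-like and astrocyte-like expression. Ephb1, which encodes an ephrin receptor, rose from 6.61 ± 0.519 to 102 ± 9.08, and Fgfr3, which encodes a growth factor receptor, from 18.7 ± 10.2 to 359.8 ± 43.8 (SD, n = 2 each). Sox9, a transcription factor gene of glial progenitors, rose from 2605 ± 332 to 11060.0 ± 260.4, and Pax6, one of forebrain progenitors, from 18.3 ± 3.76 to 178 ± 13.4. Of 37 proneural members, 20 rose, 3 fell and 14 did not pass, and 23 and 4 adjusted over the list alone (median 1.47, camera adjusted p = 2.83e-04, adjusted p = 0.354 with an estimated correlation). Of 44 classical members, 17 rose, 5 fell and 22 did not pass, and 19 and 5 adjusted over the list alone (median 0.77, camera adjusted p = 7.27e-03, adjusted p = 0.412 with an estimated correlation). Of 27 neural stem cell genes, 17 rose, 6 fell and 4 did not pass, and 18 and 6 adjusted over the list alone (median 2.09, camera adjusted p = 2.9e-03, adjusted p = 0.412 with an estimated correlation). The 6 that fell were Hes1, Tnc, Cd9, Prom1, Id1 and Nes, named after their values were seen. Hes1, a Notch target, fell from 633 ± 35.5 to 145 ± 3.17. The median change from sgCtrl replicate 2 to replicate 1 was also upward, at 0.461, 0.414 and 0.584 for these 3 lists. On the same genes, 1 and 0 proneural, 0 and 0 classical and 1 and 0 stem cell members passed as higher without sgFosl1 replicates 1 and 2, and 0 and 0, 0 and 0, and 2 and 0 as lower. Without sgCtrl replicate 2 the classical median was 0.436, and without sgCtrl replicate 1 the proneural members lower were 5. The classical list was lost with fry (adjusted p = 0.0717).

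Markers of astrocytes, oligodendrocyte lineage and neurons were also mostly higher. Sparcl1, which encodes a secreted glycoprotein of astrocytes, rose from 247 ± 195 to 3462 ± 364, and Cst3, which encodes cystatin C, from 885 ± 393 to 4598 ± 465 (SD, n = 2 each). Bcan, which encodes brevican of the brain matrix, rose from 329 ± 346 to 7360.2 ± 923, and Cnp, a myelin enzyme gene, from 34.3 ± 19.1 to 402 ± 112. Tubb3, which encodes a neuronal tubulin, rose from 45.3 ± 0.783 to 408 ± 2.72, and Gad1, which encodes a GABA-synthesising enzyme, from 25.7 ± 14.3 to 459 ± 88.2, whereas the neurofilament gene Nefl fell (log2 change −6.09 ± 0.50 SE). Of 25 astrocyte genes, 17 rose, 0 fell and 8 did not pass, and 22 rose adjusted over the list alone (median 2.5, camera adjusted p = 8.96e-07, adjusted p = 0.395 with an estimated correlation). Of 21 oligodendrocyte lineage genes, 15 rose, 2 fell and 4 did not pass, and 17 and 3 adjusted over the list alone (median 3.17, camera adjusted p = 8.96e-05, adjusted p = 0.342 with an estimated correlation). Of 28 neuronal genes, 20 rose, 4 fell (Nefl, Nefm, Gad2 and Gap43) and 4 did not pass, and 20 and 5 adjusted over the list alone (median 2.54, camera adjusted p = 6.33e-05, adjusted p = 0.342 with an estimated correlation). In sgCtrl replicate 1 these lists lay above sgCtrl replicate 2 by medians of 1.63, 1.16 and 0.847. On the same genes, 0 and 0 astrocyte, 1 and 0 oligodendrocyte and 1 and 2 neuronal members passed as higher without sgFosl1 replicates 1 and 2, and 0 and 0, 0 and 0, and 3 and 1 as lower. Without sgCtrl replicate 2, 2 neuronal members passed as lower. The Bcan call was lost without the low-value filter (adjusted p = 0.056), and the astrocyte list with fry (0.0828).

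**Figure D2:**
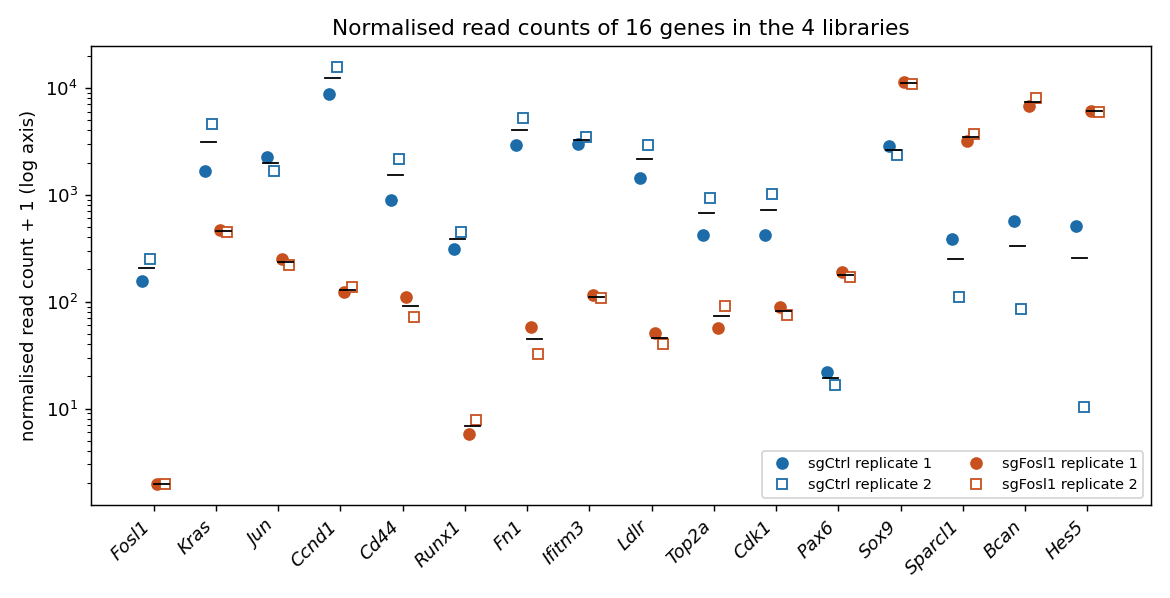
Normalised read count + 1 on a log axis for 16 genes in the 4 libraries, with sgCtrl in blue and sgFosl1 in orange, replicate 1 as filled circles, replicate 2 as open squares and group means as black bars. Before 1 was added, Fosl1 had values of 156 and 251 in sgCtrl and near 0.97 in sgFosl1. Hes5 had 506 and 9.36 in sgCtrl and 6126 and 5937 in sgFosl1.

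Output genes of the MAPK cascade and targets of the YAP and TEAD regulators were mostly lower. Ccnd1, which encodes the G1 cyclin D1, fell from 12274 ± 4917 to 129 ± 8.44, and Spry1, a feedback inhibitor gene of receptor kinase signalling, from 1133 ± 253 to 139.9 ± 8.66 (SD, n = 2 each). Axl, which encodes a receptor kinase, fell from 1754 ± 448 to 99.7 ± 17.6, and Amotl2, a regulator gene of the Hippo pathway, rose from 115 ± 15.2 to 789 ± 207. Of 31 MAPK genes, 21 fell, 1 rose and 9 did not pass, and 24 and 1 adjusted over the list alone (median −1.77, camera adjusted p = 3.88e-08, adjusted p = 0.249 with an estimated correlation); the list holds Fosl1 itself. Of 22 YAP and TEAD targets, 14 fell, 2 rose and 6 did not pass, with the same counts adjusted over the list alone (median −1.84, camera adjusted p = 4.83e-04, adjusted p = 0.337 with an estimated correlation). Of 23 TGF-beta and BMP genes, 12 fell, 3 rose and 8 did not pass, and 12 and 4 adjusted over the list alone (median −1.15, camera adjusted p = 0.0271, adjusted p = 0.296 with an estimated correlation). Tgfbr2, which encodes a TGF-beta receptor, fell from 460.1 ± 167 to 36.3 ± 17.1, and Id4, a BMP target, rose from 6.59 ± 1.96 to 136 ± 36.1. Without sgFosl1 replicates 1 and 2, with the same genes, 6 and 5 MAPK, 5 and 3 YAP and TEAD and 3 and 0 TGF-beta and BMP members passed as lower, and 0 and 0, 1 and 1, and 0 and 0 as higher. Without sgCtrl replicate 1, 2 MAPK and 6 TGF-beta and BMP members passed as higher. The TGF-beta and BMP call was lost without sgCtrl replicate 1 (adjusted p = 0.137 with the same genes and 0.923 with the filter reapplied), without sgCtrl replicate 2 with the filter reapplied (0.278), with DESeq2 (0.0585) and with a filter at 50 (0.733), where the median was 0.199 while the test still pointed down.

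Most G2 and M phase genes and 23 of 42 S phase genes were lower in sgFosl1, and none of either list rose in the main test. Cdt1, a replication licensing gene, fell from 855 ± 144 to 57.6 ± 13.1, and E2f1, a transcription factor gene of S phase entry, from 381 ± 114 to 23.7 ± 2.1 (SD, n = 2 each). Top2a, which encodes a topoisomerase of dividing cells, fell from 679 ± 363 to 72.6 ± 23.4, and Cdk1, the mitotic kinase gene, from 715 ± 424 to 81.3 ± 9.45. Of 42 S phase genes, 23 fell and 19 did not pass, and 25 fell adjusted over the list alone (median −1.44, camera adjusted p = 8.96e-07, adjusted p = 0.412 with an estimated correlation, fry adjusted p = 0.0816). Of 41 G2 and M phase genes, 35 fell and 6 did not pass, and 37 fell adjusted over the list alone (median −2.14, camera adjusted p = 3.23e-10, adjusted p = 0.342 with an estimated correlation). In sgCtrl replicate 1 these lists lay below sgCtrl replicate 2, with median differences of −0.892 and −0.95. Of 15 cell cycle inhibitors, 6 fell, 5 rose and 4 did not pass, and 8 and 5 adjusted over the list alone (median −0.86, camera adjusted p = 0.281; 0.633 with an estimated correlation); Cdkn2b fell from 387 ± 2.41 to 34.4 ± 13 and Rb1 rose from 105 ± 6.07 to 252 ± 19.4. Of 24 p53 targets, 10 fell, 3 rose and 11 did not pass, also over the list alone, and the list did not pass (median −0.595, camera adjusted p = 0.0892; 0.342 with an estimated correlation), though it did with fry (0.0246), without a filter (0.0449) and without sgFosl1 replicate 1 (0.0495 with the same genes). With the same genes tested, 13 S phase and 15 G2 and M phase genes fell without sgCtrl replicate 2, and 5 p53 targets rose without sgCtrl replicate 1. Without sgFosl1 replicates 1 and 2, 2 and 2 S phase, 0 and 0 G2 and M phase, 2 and 1 inhibitor and 2 and 0 p53 target genes passed as lower, and 0 and 0 inhibitors and p53 targets as higher, with Rb1 at an adjusted p of 0.124 and 0.105.

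Interferon response and inflammatory genes were mostly lower. Ifitm3, which encodes an antiviral membrane protein, fell from 3226 ± 338 to 110.4 ± 3.92, Isg15, a ubiquitin-like interferon product, from 326 ± 124 to 4.36 ± 2.05, and the chemokine gene Cxcl14 from 179.6 ± 5.34 to 3.87 ± 0.0067 (SD, n = 2 each). Of 30 interferon genes, 25 fell, 0 rose and 5 did not pass, and 28 fell adjusted over the list alone (median −3.43, camera adjusted p = 3.76e-11, adjusted p = 0.249 with an estimated correlation). Some members, such as Ifit3 and Ifit3b or H2-K1 and H2-D1, have near-identical copies, and their single values are uncertain. Of 41 inflammatory genes, 21 were tested. Of these 21, 16 fell, 1 rose (Vcam1) and 4 did not pass, and 17 and 2 adjusted over the list alone. The inflammatory median was −2.97, or −2.94 with genes lacking reads at their bound (camera adjusted p = 6.76e-06, adjusted p = 0.28 with an estimated correlation). The interferon list differed by a median of −0.282 between sgCtrl replicates 1 and 2. On the same genes, 14 interferon genes fell without sgCtrl replicate 2, and 12 and 7 interferon and 6 and 4 inflammatory genes without sgFosl1 replicates 1 and 2. Without sgCtrl replicate 1, 2 inflammatory genes rose, and without either sgFosl1 library 0 did.

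Genes of sterol synthesis, glycolysis, amino acid stress and oxidative stress were mostly lower. Ldlr, which encodes the receptor for low-density lipoprotein, fell from 2161 ± 1044 to 44.5 ± 8.14, and the hexokinase gene Hk2 from 397 ± 91.2 to 13.6 ± 1.35 (SD, n = 2 each). Mthfd2, a mitochondrial folate enzyme gene, fell from 1309 ± 932 to 30.5 ± 3.48, Fth1, which encodes ferritin heavy chain, from 13864 ± 642 to 2390 ± 229, and Gnl3, a nucleolar protein gene, from 715 ± 130.4 to 267 ± 12.6. Of 26 cholesterol genes, 21 fell and 5 did not pass, and 22 fell adjusted over the list alone (median −1.64, camera adjusted p = 1.94e-09, adjusted p = 0.249 with an estimated correlation). Of 34 glycolysis and hypoxia genes tested, 18 fell, 5 rose and 11 did not pass. Adjusted over the list alone, 22 fell and 7 rose (median −1.26, camera adjusted p = 7.53e-04, adjusted p = 0.337 with an estimated correlation). Below the filter and not in these counts were Gapdh, with at most 4.16 in any library, Pgam1, with at most 1.04, and Car9. Of 37 ATF4 and unfolded protein response genes, 29 fell and 8 did not pass, and 31 fell adjusted over the list alone (median −2.01, camera adjusted p = 3.76e-11, adjusted p = 0.337 with an estimated correlation). Of 21 NRF2 targets, 12 fell and 9 did not pass, and 13 fell adjusted over the list alone (median −1.28, camera adjusted p = 8.96e-05, adjusted p = 0.249 with an estimated correlation). Of 38 MYC and ribosome biogenesis genes, 20 fell and 18 did not pass, and 24 fell adjusted over the list alone (median −0.901, camera adjusted p = 3.98e-07, adjusted p = 0.372 with an estimated correlation, fry adjusted p = 0.0645). In sgCtrl replicate 1 the ATF4, MYC and glycolysis lists lay below sgCtrl replicate 2, with median differences of −0.859, −0.516 and −0.431. On the same genes, 11 MYC genes fell without sgCtrl replicate 2. Without sgFosl1 replicates 1 and 2, 4 and 2 cholesterol, 3 and 3 glycolysis, 5 and 2 ATF4, 2 and 1 NRF2 and 0 and 0 MYC genes passed as lower. Glycolysis and hypoxia genes that passed as higher were 2 without sgCtrl replicate 2 and 0 without either sgFosl1 library.

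Few ribosomal protein and mitochondrial genes passed the test. Of 76 ribosomal protein genes, 5 fell (Rps2, Rps24, Rpl12, Rplp1 and Fau), 0 rose and 71 did not pass, and 0 passed adjusted over the list alone (median −0.13, camera adjusted p = 0.239; 0.633 with an estimated correlation); many have pseudogene copies that can take reads. The count lower was 7 without sgCtrl replicate 1 and 1 without sgCtrl replicate 2 with the same genes tested. Rps2, Rps24, Rpl12 and Rplp1 each lost their call without the filter (adjusted p from 0.0544 to 0.0934) and with limma without trend (0.0567 to 0.0917), and Rplp1 also with equal totals (0.0758) and quantile normalization (0.0556). Of 10 mitochondrially encoded genes, 3 fell (mt-Nd6, mt-Rnr2 and mt-Nd2) and 7 did not pass, also over the list alone (median −0.271, camera adjusted p = 0.256; 0.633 with an estimated correlation), and without sgCtrl replicate 1 the median was −0.644 and the list passed with the filter reapplied (0.045). Without sgFosl1 replicate 2 the median was −0.475. Without the filter, mt-Rnr2 (0.0586) and mt-Nd2 (0.0997) lost their call, as did mt-Nd2 with limma without trend (0.0618) and mt-Rnr2 without sgCtrl replicate 1 with the same genes tested (0.0603). Going the other way, mt-Co1 had 1826 ± 208 in sgCtrl and 2920.0 ± 569 in sgFosl1 (SD, n = 2 each) and did not pass (limma, adjusted p = 0.0596). It passed as higher with equal totals (0.0325), quantile normalization (0.0233) and robust limma (0.0469), and with the filter reapplied without sgCtrl replicate 1 (0.0349) or replicate 2 (0.0101). The mitochondrial share of counted reads was 5.99% and 6.37% in sgCtrl and 4.59% and 5.81% in sgFosl1. Of this list, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8 and mt-Nd4l had no read in any library. The share and the list result therefore hold nothing from these genes, and why they had no reads was not tested. Of 20 genes of dissociation and heat stress, 11 fell, 1 rose (Btg2) and 8 did not pass, and 12 and 1 adjusted over the list alone (median −1.16, camera adjusted p = 1.1e-03, adjusted p = 0.249 with an estimated correlation). Without sgFosl1 replicates 1 and 2, 0 and 0 ribosomal, 0 and 0 mitochondrial and 2 and 1 stress genes passed as lower with the same genes tested, and 0 as higher. The ribosomal median was then −0.082 and −0.206.

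Few markers of other cell types reached the filter, which needs 2 libraries. Of those below it, chosen after their values were seen, the pericyte and fibroblast genes Rgs5, Col3a1 and Postn were at 127.5, 96.7 and 43.8 in sgCtrl replicate 1 and at most 9.36 in any other library. Pdgfrb was also highest in sgCtrl replicate 1 (22.9). In that library Col1a1, Col1a2, Acta2, Tagln, Des, Kcnj8, Abcc9, Anpep and Lum of the same list had no read. The endothelial genes Flt1 and Ly6c1 were at 78 and 23.9 in sgCtrl replicate 2 and at most 8.97 in any other. Others of the endothelial list did not follow them. Cldn5, Tie1, Erg, Sox17 and Sox18 had no read in any library, and Tek was higher in sgCtrl replicate 1 (13.95) than in replicate 2 (3.12). Of 5 fibroblast and pericyte markers, 4 fell (Prrx1, Pdpn, Twist1 and Dcn) and Cspg4 did not pass, also over the list alone (median −3.69, or −2.82 with genes lacking reads at their bound, camera adjusted p = 2.94e-03, adjusted p = 0.296 with an estimated correlation), and 2 and 2 passed as lower without sgFosl1 replicates 1 and 2. Pdpn, which is also expressed by glia, fell from 3656 ± 167 to 824 ± 24.7 (SD, n = 2 each). Lists with fewer than 5 tested members had no list test. The 2 tested microglia and macrophage genes did not pass, with Hexb at 145 ± 23.1 and 95.9 ± 6.68 and Cd68 at 12.8 ± 8.31 and 15.5 ± 0.027 in sgCtrl and sgFosl1. The 1 tested endothelial gene, Egfl7, fell from 30 ± 1.25 to 3.87 ± 0.0067, and the 1 epithelial gene, Cdh1, from 16.3 ± 1.94 to 2.42 ± 2.06. Of 3 tested ependymal genes, S100b, also an astrocyte gene, rose from 28.1 ± 25.1 to 117 ± 39.9, while Foxj1 (5.48 and 13.6) and Tppp3 (22.2 and 14.5) did not pass. Without sgCtrl replicate 1, Foxj1 passed as higher (log2 change 3.83 against 2.04 with all libraries, adjusted p = 0.0124 with the same genes tested and 0.000258 with the filter reapplied), and Hexb passed as lower with the filter reapplied (0.0326). The calls of Egfl7, Cdh1 and S100b were each lost without either sgFosl1 library, and those of Cdh1 and S100b also without the filter (adjusted p = 0.0765 and 0.135) and without sgCtrl replicate 2 with the same genes tested (0.0972 and 0.113). Cdh1 was lost with DESeq2 (0.0573) and without sgCtrl replicate 1 with the same genes tested (0.0659), and S100b with limma without trend (0.072) and robust limma (0.0543).

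**Figure D3:**
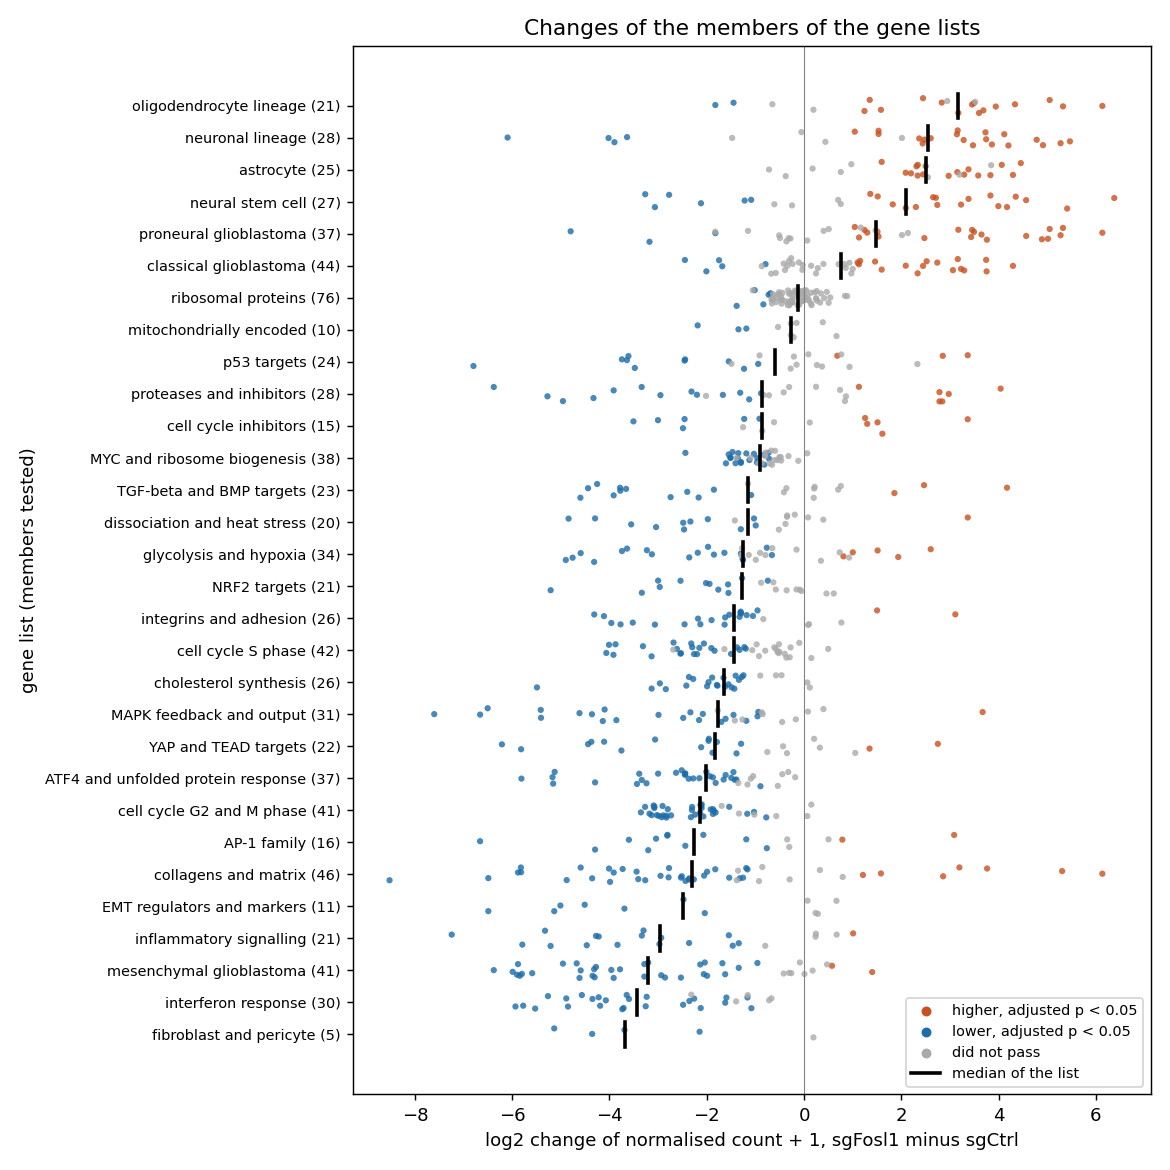
Log2 change (sgFosl1 minus sgCtrl) of each tested member of the gene lists with at least 5 tested members, 1 point per gene and 1 row per list, with a black bar at the list median. Medians run from 3.17 for oligodendrocyte lineage to −3.69 for fibroblast and pericyte markers, and colours mark members higher, lower or not passed at a limma adjusted p below 0.05.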

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

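Leaving out a library with the same genes tested was chosen after the data were seen; the other alternatives were planned. The Fosl1 log2 change kept its direction and its call in every alternative that tested it, from −6.32 to −7.00 when a library was left out; with the filter reapplied, Fosl1 was no longer tested when an sgCtrl library was left out, because 1 library then remained above the filter. Changed genes numbered from 3393 to 4726 over the other pseudocounts, the filter at 50, the scalings, the limma settings, edgeR (4425), DESeq2 (3925), the minimum log2 change and the block. Without a filter, 2237 genes changed (918 higher, 1319 lower), with 19198 genes tested. With a library left out and the filter reapplied, the range was 840 to 5816 changed, 165 to 3185 higher and 675 to 2631 lower. These fits also changed which genes were tested (10946 to 11079), and when an sgCtrl library was left out the mesenchymal list shrank from 41 to 26 tested members. With the same genes, the counts were 410 (38 higher, 372 lower) without sgFosl1 replicate 1, 267 (25 higher, 242 lower) without sgFosl1 replicate 2, 4861 (2535 higher, 2326 lower) without sgCtrl replicate 1 and 3039 (1502 higher, 1537 lower) without sgCtrl replicate 2. The low counts without an sgFosl1 library follow from their construction, since the lone sgFosl1 library is assumed to vary like the sgCtrl pair. The log2 differences had an SD of 0.83 within the sgCtrl pair and 0.471 within the sgFosl1 pair. When an sgCtrl library is left out, the lone sgCtrl library is assumed to vary like the closer sgFosl1 pair, which can raise those counts. The main test likewise uses 1 spread per gene for both groups. All calls shared with the main test had the same direction in each alternative. The higher share was 47.7%, and no scaling moved it by over 10 points, but leaving out an sgFosl1 library did, to 19.8% and 19.6%, or 9.27% and 9.36% with the same genes. Equal totals moved the median of all genes from 0.0039 to 0.105 on the log2 scale, and each tested list had a median larger in size than that shift. List medians without sgCtrl replicates 1 and 2 depended on the filter. The mesenchymal ones were −1.89 and −1.55 with the filter reapplied, against −3.4 and −2.85 with the same genes. AP-1 medians were −1.08 and −1.6, against −1.87 and −2.6. Interferon medians were −1.91 and −2.06, against −3.73 and −3.31, and inflammatory ones −1.32 and −1.62, against −3.65 and −2.8.

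The camera result of the proteases and inhibitors turned without sgCtrl replicate 1 with the filter reapplied (medians over left-out libraries from −1 to 0.121). With the same genes it did not (−0.759), so the turn was seen only with the reapplied filter. With that filter the median stayed below 0 when any other library was left out. The camera result of the ribosomal proteins turned without sgFosl1 replicate 1 with the filter reapplied (medians from −0.206 to −0.082, never above 0) and not with the same genes. Neither turned list result passed. Cd68, which did not pass, ranged from −0.258 to 1.05 (log2) with the filter reapplied and was −0.258 with the same genes without sgCtrl replicate 1. The value is the same in both fits, so it follows from leaving out that library, which held 7 Cd68 reads against 18 in sgCtrl replicate 2 and 16 in each sgFosl1 library. With an estimated correlation 25 list calls were lost, the mesenchymal list at an adjusted p of 0.296 and the proneural list at 0.354. Fry lost 4 and added 2. Among the named genes, 23 and 26 calls were lost without sgFosl1 replicates 1 and 2 with the filter reapplied and 63 and 80 with the same genes, and 16 without a filter. The groups share replicate numbers, and the labels do not say whether same-numbered libraries belong together. Their deviations correlated at r = 0.0376 across 11701 genes. This 1 correlation shows no shared deviation but cannot show how the libraries were prepared. The replicate block gave 4726 changed genes (2266 higher, 2460 lower). Under the block, the Rplp1 call ended (adjusted p = 0.0577) and Trp53 (0.0257) and mt-Co1 (0.0498) passed, as each also did under other settings. In the simulation, 2-fold changes were mostly not detectable, with 22% recovered. It placed changes only in genes with a mean of at least 50, used 1 dispersion for both groups and did not vary the depth.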

Other observations

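The regional identity genes and the tests of a label swap, of Kras and of chromosomes 4, 10, 19 and X were chosen only after the result was seen. Regional identity genes of the embryonic brain moved in both directions. Of 53 transcription factor genes looked up, 28 were tested, 10 were higher and 10 lower in sgFosl1 (limma, adjusted p below 0.05). Foxg1, a telencephalon gene, was 46.3 ± 36 in sgCtrl and 656 ± 2.98 in sgFosl1 (SD, n = 2 each; adjusted p = 0.00388), and Dbx2 was 4.51 ± 4.9 and 220 ± 1.75 (0.00328). Nkx2-1, a ventral forebrain gene, was 178 ± 51.5 and 3.87 ± 0.0067 (0.00108), Otx2 was 194 ± 35.1 and 6.77 ± 5.47 (0.00288), Msx1 309 ± 176 and 2.9 ± 1.36 (0.00138), and Emx2 790 ± 72.5 and 179 ± 25 (0.00175). Lhx2 and Hoxa5 did not pass (140 and 169; 149 and 177).

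In a first pattern, sgCtrl replicate 1 lay between sgCtrl replicate 2 and the sgFosl1 libraries. Rgs5 and Col3a1 of the pericyte and fibroblast list were high in it alone (127.5 and 96.7), but Col1a1, Acta2 and Des of that list had no read in it. A single share of sgFosl1-type cells in that library would give the same share from genes higher and lower in sgFosl1. The median share was 0.126 (bootstrap interval over genes 0.115 to 0.132) over 482 higher genes and 0.41 (0.368 to 0.438) over 480 lower genes, a difference of 0.284. Shares of lower genes were spread widely, with quartiles of 0.00836 and 0.599. The genes were chosen by their distance from sgCtrl replicate 2, whose value also enters the share. Spread between the sgCtrl libraries can therefore raise the share of lower genes, by an amount not measured. The difference thus does not settle whether 1 share was the whole cause. A swap between the groups is argued against by the 157 Fosl1 reads in sgCtrl replicate 1, with 1 read in each sgFosl1 library. Separate cultures or clones that differ within a group stay open and were not tested.

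In a second pattern, Kras reads and MAPK output genes were both lower in sgFosl1. If the Kras level alone set these genes, the sgCtrl library with 2.77 times the normalised Kras value of the other should be higher for most of them. It was higher for 12 of the 21 members called lower, or 57.1%, and 2 libraries with different Kras values are too few to decide, so the Kras level and the guide cannot be told apart for these genes. Every comparison here is between the same groups, so this limit holds for the other genes and lists too. A biological effect of Fosl1 on the MAPK output list stays open.

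In another pattern, tested genes of some chromosomes were shifted together. The median change differed from that of the other chromosomes by 0.385 on chromosome 14, 0.261 on chromosome 2, 0.251 on X, −0.251 on chromosome 4 and −0.333 on chromosome 19 (permutation p = 0.0001 each, the smallest that 10000 shuffles can give, 0.0004 adjusted over 20 chromosomes), and by −0.163 on chromosome 10 (p = 0.0023, 0.00767 adjusted), where genes are not independent replicates. A copy number difference over all of chromosome 14 is argued against by the first 123 of its 368 tested genes in chromosome order, at −0.288 (interval −0.557 to −0.126). Its middle and last parts were shifted upward, at 0.882 (0.72 to 1.04) and 0.491 (0.217 to 0.737). A difference over part of chromosome 14 therefore stays open and was not tested. Over 3 such parts and the inner quartile, the shift kept 1 sign on the 5 other shifted chromosomes, of which chromosome 19 holds Fosl1. The smallest size was 0.2 on chromosome 2, 0.153 on X, −0.106 on chromosome 4, −0.113 on chromosome 10 and −0.25 on chromosome 19. These 5 are consistent with copy number differences, but the rule tells little, since 4 of the 14 chromosomes whose shift did not pass also met it and the interval of at least 1 part included 0 on each of the 5 except chromosome 2, and shared regulation of neighbouring genes stays open and untested.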
